A study of Mus musculus with 14 samples.

How the data were processed

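Lungs of C57BL/6N male mice were taken 6 months after a single dose into the trachea of 200 µg carbon fibre per mouse, in 3 forms, or of phosphate-buffered saline. Total RNA of each lung was labelled with Cy3 and hybridized to a mouse 4-array slide of the 44K design, 1 lung per array, 14 arrays in all. Groups follow the labels: Ctrl (3 arrays), VCF (4), CCF (3) and RCF (4).

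The scanner files deposited by the authors hold intensity values per spot, made with Agilent Feature Extraction 10.7.3.1 per the file headers. They are background-subtracted and not normalized between arrays. The raw median intensity of each spot and of its local background, and other columns such as the flags for saturation and for signal well above background, come from the same software per the file headers. The table of values deposited by the authors is on a log2 scale. For 100% of its 27496 probes each column equals log2 of the processed intensity of its own array minus 1 constant, within 0.01, close to that array's 75th percentile. It holds 0 columns of other samples, and how its probes were chosen is not stated.

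The analysis used log2 of the processed intensity minus each array's 75th percentile over probes that are not controls. Spots of 1 probe were averaged, which gave 41174 probes from 43379 spots, and 1639 control spots were left out. A probe was tested if it stood well above background on at least 3 of the 14 arrays, counted without regard to group, which left 29269. Gene symbols came from the probe's RefSeq transcript, looked up in a table of mouse genes on assembly GRCm38.p6. 24844 probes matched 1 symbol (17178 genes), and 16330 did not. No coordinates were taken from it, and the array grid was built on another assembly.

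Groups were compared with limma 3.58.1 in R 4.3.3, with all 4 groups in 1 fit (10 residual degrees of freedom, 2.39 prior degrees of freedom). Tests are two-sided, with a Benjamini-Hochberg adjusted p under 0.05 over the probes tested, per comparison. The comparisons are each fibre against Ctrl, the 3 pairs of fibres, and the average of the 3 fibre groups against Ctrl. Files were read with the data.table package, version 1.17.8, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. On simulated arrays with known VCF changes, 53% of those of 1 and 89% of those of 2 (log2) were found in VCF against Ctrl. A shifted list was found, with correlation of genes not varied. Unchanged probes called were 9 in VCF against Ctrl, 3 in CCF and 16 in RCF against VCF, and 0 elsewhere.

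Before the data were examined 44 gene lists were fixed, of pathways and of cell types in or near the lung. A list was tested if at least 5 of its genes were, which 43 met. The list that was not tested is that of the thyroid. Each of 14468 genes was read at its brightest probe. Lists were tested with camera at a preset correlation of 0.01. camera with an estimated correlation and fry stand beside it. 21 lists passed in no comparison, with smallest adjusted p between 0.0565 and 0.574. The score of a list on an array is the mean over its genes of the difference from the Ctrl mean.

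Named genes were also chosen by a rule fixed before the data were examined. It takes genes that passed, had their arrays of both groups apart and stood above background in the brighter group, filled up to 5 in each direction with those of smallest p where fewer passed. It adds the 4 members with the smallest p of each list that passed, in the list's direction, and a panel of 12 genes in each comparison with Ctrl. The 2 unnamed probes and the individual arrays discussed fall outside it and were chosen after their values were seen.

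Alternatives fixed before the data were examined were normexp background correction, quantile and cyclic loess normalization, the authors' deposited table, other filters on dim probes, slide, position on the slide or replicate number as a block, a fit of only the groups compared, a trended and robust prior, array weights, other thresholds and tests, the mean over a gene's probes, and leaving out each array in turn. Normexp was planned on mean spot intensity, which the files lack, and used the median instead with an offset of 50. Added after the data were seen were a fit without 4 arrays high in liver, thymus or adipose genes, and an exact permutation test of list scores. The rule that matches list symbols to probes was also tightened after results had been seen: a current symbol without a probe is no longer replaced by an older synonym, which took 1 gene out of the liver list. Slides and scan sessions were read from the file headers, and each slide had its own session.

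The 75th percentile of the processed intensity ran from 724.7 to 1345.6 per array, the median from 48.7 to 89.8, and 25968 to 29026 probes stood well above background. No spot was saturated. Where a named gene is well above background on no array of a group, a fold is given as a lower bound, against the lowest signal that was well above background on each of that group's arrays, or the probe's own signal where that is higher. No sample was left out of the main analysis.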

Results

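RNA of 14 mouse lungs was measured on one-colour oligonucleotide arrays 6 months after a fibre suspension or vehicle had been placed in the trachea. The question was how the lung's transcripts differ after carbon fibre taken before recycling (VCF), after the carbonization step (CCF) or after the firing step (RCF), each at 200 µg per mouse, from those after phosphate-buffered saline (Ctrl). There were 3 Ctrl, 4 VCF, 3 CCF and 4 RCF arrays, each from an independent animal by the design text. The 75th percentile of the processed signal ran from 724.7 to 1345.6 intensity units, and 63.07% to 70.5% of the 41174 probes stood well above background on an array. The number of arrays limits the precision. Differences are log2 values, the first-named group minus the second, with the standard error (SE) from limma. Gene lists are said to be higher or lower where camera passed them at its preset correlation; in no comparison did a list pass with an estimated correlation.

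The arrays lay on 4 slides, each read in its own scan session. Slides 1 and 3 held 1 array of each group, slide 2 Ctrl, VCF and RCF, and slide 4 VCF, CCF and RCF but no Ctrl. Transcripts of neighbouring tissue varied between arrays. The score of 6 liver genes was 3.01 in CCF replicate 2 and 3.04 in RCF replicate 1 above the Ctrl mean, that of 5 thymus genes was 2.58 in CCF replicate 3, and that of 9 adipose genes was 2.40 in VCF replicate 1. Cardiac muscle scores ran from -2.21 in VCF replicate 4 to 2.22 in VCF replicate 1. In a fit added after the data were seen, CCF replicates 2 and 3, RCF replicate 1 and VCF replicate 1 were left out together. That leaves CCF replicate 1 as the only CCF array, so values and counts with CCF in this fit rest on 1 CCF lung. No probe passed in VCF or RCF against Ctrl or in RCF against VCF, where 7, 7 and 4 lists passed. Ctrl replicate 1 had a neutrophil score of 1.24, against -0.62 and -0.61 in the other Ctrl arrays.

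The comparison of VCF with Ctrl asks what fibre that was never recycled leaves in the lung after 6 months. Red blood cell transcripts were higher in the 4 VCF lungs than in the 3 Ctrl lungs, a list call lost with an estimated correlation (adjusted p = 0.217). Alas2, the first enzyme of haem synthesis in red cell precursors, differed by 2.27 (SE 0.44) and the alpha-globin gene Hba-a1 by 1.75 (SE 0.30). Transcripts of alveolar macrophages and of the oxidative stress response were lower, calls lost in the same way (adjusted p = 0.217 and 0.285). Mt2, a metal-binding metallothionein, differed by -0.72 (SE 0.18), Hmox1, the inducible haem-degrading enzyme, by -0.48 (SE 0.14), and Pparg, a regulator of alveolar macrophage identity, by -0.30 (SE 0.10). None of these genes passed on its own over all probes, and Hmox1 differed by -0.30 without Ctrl replicate 1.

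Over the 29269 probes, 3 passed in limma, all higher in VCF. The plain 2-sample test with adjustment passed 0 probes in each comparison. The named one was Olfr1495, an olfactory receptor gene (probe A_51_P192639), at 2.52 (SE 0.28, adjusted p = 0.0277), higher in 4 of 4 VCF arrays. Its signal was well above background in 4 of 4 VCF arrays and 1 of 3 Ctrl arrays, so the size of its difference rests on Ctrl signals near background. The other 2 carry no gene name and differed by 2.05 and 2.60 (adjusted p = 0.0337 for both). At an unadjusted p under 0.05, 2417 probes were found against 1463 expected by chance, which is the number in each comparison. Olfr1495 differed by 2.42 with the slide as a block (adjusted p = 0.119) and by 3.06, 2.66 and 1.77 within slides 1, 2 and 3. The call also ended with normexp background correction (0.59), quantile normalization (2.38), cyclic loess normalization (2.45) and a fit of only VCF and Ctrl (2.52). The call for Olfr1495 ended without Ctrl replicate 1 (2.68), Ctrl replicate 2 (2.44), Ctrl replicate 3 (2.44), VCF replicate 1 (2.50), VCF replicate 3 (2.39), VCF replicate 4 (2.53), RCF replicate 1 (2.52) or RCF replicate 3 (2.52). The count of probes fell to 0 without each of these 8 arrays, to 1 without RCF replicate 2, and was 7 without CCF replicate 3 and 16 without CCF replicate 1.

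The 9 measured red blood cell genes were all higher, by a mean of 1.21 (adjusted p = 3.57e-13, or 0.217 with an estimated correlation). Adjusted over the list alone 6 of them passed, and over all genes tested 0 did. The mean was 1.30 with the slide as a block and 1.84, 1.38 and 0.73 on slides 1, 2 and 3, and no left-out array ended this call. Of 15 alveolar macrophage genes 15 were lower, by a mean of -0.29 (adjusted p = 4.67e-05, or 0.217 with an estimated correlation), again with each array left out in turn. Besides Pparg they included Krt79 -0.58 (SE 0.18), Krt19 -0.47 (SE 0.16) and Plet1 -0.36 (SE 0.14), markers of that cell type in mice. The mean was -0.26 with the slide as a block and -0.17, -0.22 and -0.41 on slides 1, 2 and 3. Of 23 oxidative stress genes 21 were lower, by a mean of -0.26 (adjusted p = 3.6e-05, or 0.285 with an estimated correlation). Adjusted over the list alone 1 of them passed. The mean was -0.27 with the slide as a block and -0.15, -0.12 and -0.57 on slides 1, 2 and 3. All 27 cell division genes were lower, by a mean of -0.27 (adjusted p = 4.52e-05, or 0.757 with an estimated correlation). Examples are the mitotic kinase Aurka at -0.41 (SE 0.20) and the replication factor Mcm5 at -0.46 (SE 0.24), which stood at -0.26 and -0.28 without Ctrl replicate 1, and Aurka at 0.11 on slide 1.

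Lists of inflammation followed the same direction. The mean difference was -0.23 for interferon response genes (adjusted p = 0.00357), -0.17 for phagocyte genes (adjusted p = 0.0215), -0.33 for monocyte genes (adjusted p = 0.0267), -0.32 for chemokine genes (adjusted p = 0.0397) and -0.41 for acute phase genes (adjusted p = 0.0418). With an estimated correlation these gave adjusted p = 0.757, 0.757, 0.778, 0.757 and 0.72 in that order. Members with the smallest p were Ifit3, an interferon-induced gene, at -0.47 (SE 0.16), Lgals3, a lectin of macrophages, at -0.44 (SE 0.18), Ccl17, a T cell attractant, at -0.69 (SE 0.31), and Cfb, a complement factor, at -0.59 (SE 0.24). Ccl17 stood at -0.35 without Ctrl replicate 1 and 0.48 on slide 1. Adipose genes had a mean difference of 0.69 (adjusted p = 0.0215, or 0.757 with an estimated correlation), with 2.40 in VCF replicate 1 alone against the Ctrl mean. In all, 10 of 43 lists passed, 2 up and 8 down, and with an estimated correlation camera passed 0, where 3 had an unadjusted p under 0.05; fry passed 0. With the slide as a block the means (adjusted p) were -0.16 for phagocyte (0.0262), -0.26 for chemokine (0.101), -0.42 for acute phase (0.0296), -0.16 for interferon response (0.0448), -0.22 for cell division (0.000909), -0.27 for monocyte (0.101) and 0.45 for adipose (0.0953). Within slides the direction turned for phagocyte (0.03 on slide 1), chemokine (0.50 on slide 1), interferon response (0.33 on slide 1), cell division (0.24 on slide 1), monocyte (0.45 on slide 1) and adipose (-0.54 on slide 1). Among the other settings, calls also ended with quantile normalization for phagocyte, chemokine and monocyte; array weights for phagocyte, chemokine, acute phase, interferon response and monocyte; cyclic loess normalization for chemokine and acute phase; the authors' deposited table for adipose. Leaving out Ctrl replicate 1 ended the list calls for phagocyte (-0.09), chemokine (-0.29), acute phase (-0.33), oxidative stress (-0.13), interferon response (-0.11), cell division (-0.15), monocyte (-0.09) and adipose (0.69). Calls ended without Ctrl replicate 2 for phagocyte (-0.12), chemokine (-0.05), acute phase (-0.37), interferon response (-0.18) and adipose (0.42). With VCF replicate 1 left out the calls ended for chemokine (-0.23), interferon response (-0.14), monocyte (-0.25) and adipose (0.12). Leaving out VCF replicate 2 ended the list calls for phagocyte (-0.10), chemokine (-0.25), monocyte (-0.22) and adipose (0.71). Calls ended without VCF replicate 3 for acute phase (-0.36). With VCF replicate 4 left out the calls ended for acute phase (-0.44). The list count was 3 without Ctrl replicate 1, 18 without Ctrl replicate 3 and 17 without VCF replicate 3.

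The comparison of CCF with Ctrl asks the same of fibre recovered by carbonization. Alveolar macrophage transcripts were lower in the 3 CCF lungs than in the 3 Ctrl lungs, a list call lost with an estimated correlation (adjusted p = 0.0817). Ear1, a ribonuclease gene that mouse alveolar macrophages express, differed by -0.93 (SE 0.20), Pparg by -0.47 (SE 0.11) and Fabp1, a fatty acid carrier, by -0.67 (SE 0.22). Eosinophil transcripts were lower too, with Ear6, a ribonuclease gene of that family, at -0.96 (SE 0.19) and Siglecf, a surface receptor of eosinophils and alveolar macrophages, at -1.18 (SE 0.55). Without CCF replicate 2 Siglecf differed by -0.42, and on slide 3 by 0.14. The eosinophil call was lost too (adjusted p = 0.322). Red blood cell transcripts were higher, with Alas2 at 1.55 (SE 0.48) and Hba-a1 at 1.23 (SE 0.32), and the oxidative stress list, which holds Mt2 and Mt1, was lower, with Mt2 at -0.89 (SE 0.19) and Mt1 at -0.66 (SE 0.22). The red blood cell and oxidative stress calls had adjusted p = 0.496 and 0.435 with an estimated correlation, and none of these genes passed over all probes. Without CCF replicate 1 Alas2, Hba-a1 and Mt1 differed by 0.94, 0.81 and -0.43.

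No probe passed in limma, where 1930 had an unadjusted p under 0.05 and the smallest adjusted p was 0.217, that of Olfr1495 at 2.22 (SE 0.30). Without RCF replicate 2, 1 probe passed. Of 15 alveolar macrophage genes 15 were lower, by a mean of -0.49 (adjusted p = 5.74e-08, or 0.0817 with an estimated correlation). fry passed this list (adjusted p = 0.00921), and adjusted over the list alone 4 genes passed, against 0 over all genes tested. The mean was -0.42 with the slide as a block and -0.47 and -0.30 on slides 1 and 3, and the call held with each array left out in turn. All 9 red blood cell genes were higher, by a mean of 0.73 (adjusted p = 3.16e-06, or 0.496 with an estimated correlation), and the call held with each array left out. The mean moved to 0.28 without CCF replicate 1 and to 1.00 without CCF replicate 3. Adjusted over the list alone 3 passed. The mean was 0.92 with the slide as a block and 0.74 and 1.23 on slides 1 and 3. Of 23 oxidative stress genes 19 were lower, by a mean of -0.28 (adjusted p = 0.000185, or 0.435 with an estimated correlation). The mean was -0.32 with the slide as a block and -0.24 and -0.48 on slides 1 and 3. All 6 eosinophil genes were lower, by a mean of -0.66 (adjusted p = 0.0138, or 0.322 with an estimated correlation), with -0.58 with the slide as a block and -0.16 and -1.03 on slides 1 and 3.

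Il5ra, the receptor chain for the eosinophil growth factor interleukin 5, was at background on 3 of 3 CCF arrays and at least 1.57-fold higher in Ctrl. Phagocyte genes, which serve lysosomes and lipid uptake, differed by a mean of -0.26, and smooth muscle genes by 0.19. Both had adjusted p = 0.0138, or 0.607 with an estimated correlation. Examples are Atp6v0d2, a subunit of the lysosomal proton pump, at -0.74 (SE 0.25) and Myh11, smooth muscle myosin, at 0.26 (SE 0.19), the latter at 0.13 without CCF replicate 1 and -0.08 on slide 1. Thymus genes averaged 1.28 (adjusted p = 0.0138, or 0.496 with an estimated correlation) and liver genes 1.34 (adjusted p = 0.0138, or 0.607 with an estimated correlation), in the group that holds CCF replicates 2 and 3, whose scores for these tissues are given above. Rag1, which recombines antigen receptor genes in immature lymphocytes, was well above background on 2 of 3 CCF arrays and on 0 of 3 Ctrl arrays, at least 5.56-fold higher, and 1.68-fold without CCF replicate 3. Fgb, a fibrinogen chain made in liver, differed by 3.14 (SE 1.57), by 1.53 without CCF replicate 2 and by -0.37 on slide 1, with signal well above background on 2 of 3 CCF and 1 of 3 Ctrl arrays. In all, 8 of 43 lists passed, 4 in each direction, and with an estimated correlation camera passed 0, where 3 had an unadjusted p under 0.05; fry passed 1. Fits with the slide as a block gave means (adjusted p) of -0.21 for phagocyte (0.0417), 0.17 for smooth muscle (0.0283), 1.30 for thymus (0.0242) and 1.16 for liver (0.0926). Within slides the direction turned for phagocyte (0.14 on slide 1), thymus (-0.16 on slide 3) and liver (-0.16 on slide 1). Other settings that ended calls were normexp background correction for phagocyte, oxidative stress, thymus and liver; quantile normalization for phagocyte; array weights for phagocyte, smooth muscle, eosinophil and liver; no filter on dim probes for smooth muscle and liver; the position on the slide as a block for eosinophil; the mean over all probes of a gene for thymus. Omitting Ctrl replicate 1 ended the list calls for phagocyte (-0.19), oxidative stress (-0.15), smooth muscle (0.12), eosinophil (-0.54), thymus (1.36) and liver (1.19). Without Ctrl replicate 2 the calls ended for phagocyte (-0.22). Dropping CCF replicate 1 ended the calls for phagocyte (-0.20), smooth muscle (0.19) and eosinophil (-0.58). Omitting CCF replicate 2 ended the list calls for phagocyte (-0.24), smooth muscle (0.14) and liver (0.50). Without CCF replicate 3 the calls ended for thymus (0.62). Thymus genes stood at 0.01 in the fit without 4 arrays, where CCF replicate 1 is the only CCF array. The number of lists that passed was 4 without Ctrl replicate 1 and 14 without Ctrl replicate 3. Normexp background correction moved the median of all probes from -0.015 to -0.226 in this comparison, and Olfr1495 then stood at -0.11, above that median but below 0.

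The comparison of RCF with Ctrl asks the same of fibre that was fired after carbonization. Genes of the circadian clock differed in opposite directions between the 4 RCF and 3 Ctrl lungs. Arntl, the clock activator also called Bmal1, was higher by 1.08 (SE 0.15), while Tef, Per2 and Ciart, whose daily peaks lie roughly opposite to that of Arntl, differed by -0.59 (SE 0.12), -0.76 (SE 0.18) and -0.98 (SE 0.31). The clock list call was lost with an estimated correlation (adjusted p = 0.171), and a second Per2 probe differed by 0.27. Mt2 differed by -1.16 (SE 0.18), and cell division genes such as Mki67, a marker of dividing cells, by -0.61 (SE 0.23). Red blood cell transcripts were higher, with Alas2 at 1.69 (SE 0.44) and Hba-a1 at 1.44 (SE 0.30). Those 2 list calls had adjusted p = 0.685 and 0.458 with an estimated correlation, and none of these genes passed over all probes.

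No probe passed in limma, where 1564 had an unadjusted p under 0.05 and the smallest adjusted p was 0.122, that of Pbld1 at 1.03 (SE 0.13). Without CCF replicate 1, 10 probes passed. Among genes with the smallest p were the growth factors Wnt2 at 0.72 (SE 0.11) and Angpt2, which acts on blood vessels, at 0.79 (SE 0.13), higher in 4 of 4 arrays, and Cars, a cysteine transfer RNA ligase, at -0.60 (SE 0.10), lower in 4 of 4. Of 18 clock genes 13 were lower. The list's mean was -0.16 and its median -0.34 (adjusted p = 0.000713, or 0.171 with an estimated correlation), and adjusted over the list alone 6 passed downward and 1 upward. In the mixed form of fry, which tests change in either direction, adjusted p = 9.03e-06. The mean was -0.13 with the slide as a block and -0.27, -0.03 and -0.19 on slides 1, 2 and 3. Within those slides Arntl differed by 1.33, 0.96 and 1.07 and Tef by -0.77, -0.63 and -0.39. All 27 cell division genes were lower, by a mean of -0.37 (adjusted p = 4e-09, or 0.685 with an estimated correlation), with -0.32 with the slide as a block and -0.26, -0.40 and -0.44 on slides 1, 2 and 3. The calls for the clock, cell division, red blood cell and alveolar macrophage lists held with each array left out in turn, while their means moved. The clock mean ran from -0.25 (without Ctrl replicate 2) to -0.10 (without Ctrl replicate 3), that of cell division from -0.58 (without Ctrl replicate 3) to -0.25 (without Ctrl replicate 1), and that of red blood cells from 0.54 (without Ctrl replicate 3) to 1.02 (without Ctrl replicate 1).

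All 9 red blood cell genes were higher, by a mean of 0.82 (adjusted p = 1.7e-06, or 0.458 with an estimated correlation). The mean was 0.91 with the slide as a block and 1.16, 0.95 and 0.42 on slides 1, 2 and 3. Adjusted over the list alone 4 genes passed, and 0 over all genes tested. Of 15 alveolar macrophage genes 14 were lower, by a mean of -0.20 (adjusted p = 0.00141, or 0.383 with an estimated correlation), with -0.17 with the slide as a block and -0.16, -0.18 and -0.23 on slides 1, 2 and 3. Oxidative stress genes were lower in 21 of 23, by a mean of -0.27 (adjusted p = 2.1e-05, or 0.383 with an estimated correlation), with -0.27 with the slide as a block and -0.12, -0.17 and -0.50 on slides 1, 2 and 3. Adjusted over the list alone 2 passed. The mean difference was -0.56 for acute phase genes (adjusted p = 0.00285), -0.74 for neutrophil genes (adjusted p = 0.00295) and -0.31 for monocyte genes (adjusted p = 0.0269). With an estimated correlation these gave adjusted p = 0.438, 0.759 and 0.759 in that order. Lcn2, an iron-trapping protein of neutrophils and epithelium, differed by -1.22 (SE 0.43), and Camp, an antimicrobial peptide, by -1.62 (SE 0.83). Camp stood at -0.96 without Ctrl replicate 1 and at 1.30 on slide 2. In all, 8 of 43 lists passed, 1 up and 7 down, and with an estimated correlation camera passed 0, where 4 had an unadjusted p under 0.05; fry passed 0. The means (adjusted p) with the slide as a block were -0.56 for acute phase (0.00162), -0.78 for neutrophil (0.00674) and -0.25 for monocyte (0.121). Within slides the direction turned for neutrophil (0.16 on slide 2) and monocyte (0.04 on slide 2). Among the remaining settings, calls ended with array weights for neutrophil and monocyte. Leaving out Ctrl replicate 1 ended the list calls for acute phase (-0.47), oxidative stress (-0.14), neutrophil (-0.12) and monocyte (-0.07). Calls ended without RCF replicate 1 for monocyte (-0.26). With RCF replicate 3 left out the calls ended for monocyte (-0.23). The list count was 19 without Ctrl replicate 3.

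**Figure D1:**
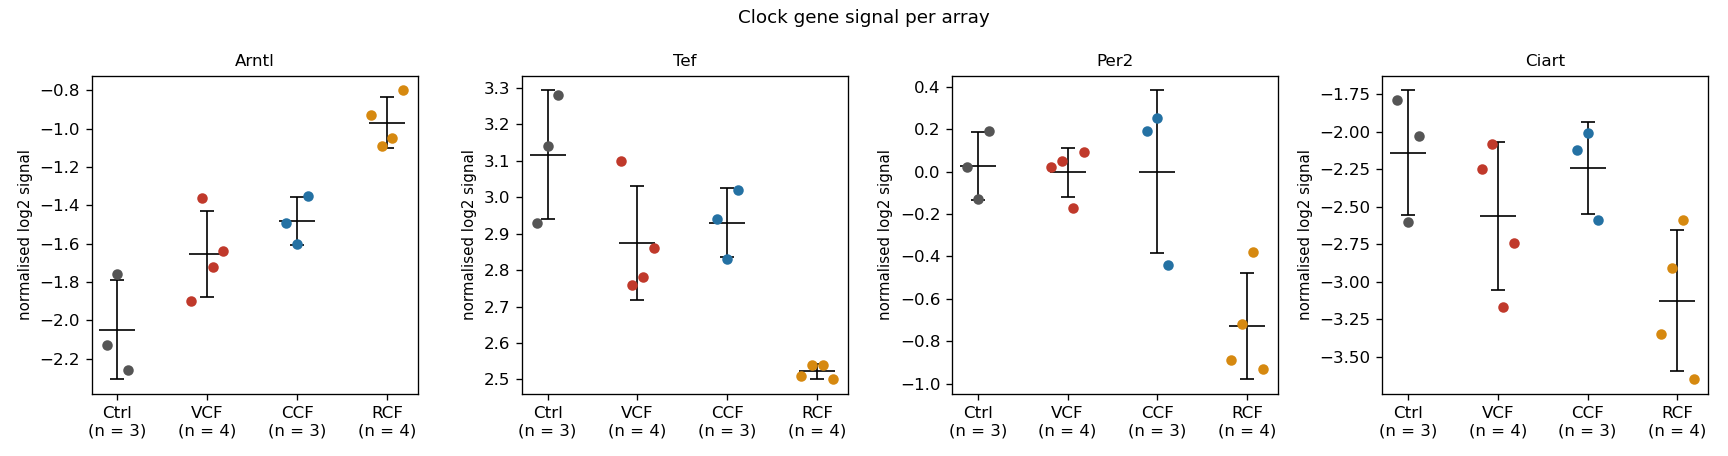
Normalised log2 signal of Arntl, Tef, Per2 and Ciart on each array by group, with bars for the mean and SD of each group. Arntl differed by 1.08 and Tef by -0.59 between RCF and Ctrl, and neither passed over all probes.

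A panel of 12 inflammation, fibrosis and stress genes was read in each comparison with Ctrl, and none passed. Values stand in the order VCF, CCF and RCF. Spp1, which encodes osteopontin, differed by 0.04 (SE 0.23), -0.40 (SE 0.25) and -0.24 (SE 0.23), where the VCF value turned negative with normexp background correction (-0.10). Ccl2, a monocyte attractant, differed by -0.35 (SE 0.28), -0.67 (SE 0.30) and -0.60 (SE 0.28), and Timp1, an inhibitor of matrix proteases, by -0.93 (SE 0.35), -0.94 (SE 0.37) and -0.96 (SE 0.35). The collagen gene Col1a1 differed by -0.07 (SE 0.26), 0.04 (SE 0.28) and 0.16 (SE 0.26), and its second probe by -0.46, 0.21 and -0.39, the last of opposite sign. Saa3, an acute phase protein, differed by -1.10 (SE 1.01), -0.49 (SE 1.08) and -1.32 (SE 1.01). Mmp12, a macrophage elastase, differed by -0.67 (SE 0.31), -0.66 (SE 0.33) and -0.28 (SE 0.31), and Gpnmb, a glycoprotein of lipid-laden macrophages, by -0.34 (SE 0.29), -0.32 (SE 0.31) and -0.16 (SE 0.29). The neutrophil attractant Cxcl1 differed by -0.44 (SE 0.59), -0.17 (SE 0.63) and -0.04 (SE 0.59), and Cdkn1a, a brake on the cell cycle, by 0.15 (SE 0.19), 0.29 (SE 0.20) and -0.01 (SE 0.19). Cyp1a1, which aryl hydrocarbons induce, differed by -1.21 (SE 0.93), -1.22 (SE 1.00) and -1.62 (SE 0.93). Without Ctrl replicate 1 its values were 0.18, 0.17 and -0.23. Of the genes named here only Timp1 kept its values within 1.5 times with each array left out, and each turned sign within a slide in at least 1 comparison. The lists of matrix and fibrosis genes (22 genes, means -0.14, -0.09 and -0.12) and of inflammatory cytokines (16 genes, means -0.23, -0.21 and -0.11) did not pass in any of these comparisons.

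The comparison of CCF with VCF asks what carbonization changes. Transcripts of T cells, natural killer cells, monocytes and neutrophils were higher after CCF (3 arrays) than VCF (4), and those of eosinophils and red blood cells lower. These calls were lost with an estimated correlation (adjusted p 0.128 to 0.866). Without CCF replicate 3 (thymus score 2.58) all but eosinophils ended (monocytes -0.03). Prf1, the pore-forming protein of killer cells, differed by 0.96 (SE 0.32), Lck, the T cell receptor kinase, by 0.60 (SE 0.26), and Ifit3 by 0.35 (SE 0.16). Alox15, a lipoxygenase of eosinophils, well above background on 1 of 3 CCF arrays, differed by -1.16 (SE 0.42) and Alas2 by -0.72 (SE 0.44), which was -0.27 without CCF replicate 3 and 0.47 on slide 3. No probe passed in limma, where 1699 had an unadjusted p under 0.05 and the smallest adjusted p was 0.709. 1 probe passed without CCF replicate 2, and 1 without RCF replicate 2.

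All 6 eosinophil genes were lower, by a mean of -0.79 (adjusted p = 0.00105, or 0.128 with an estimated correlation), with -0.75 with the slide as a block and -0.91, -0.64 and -0.49 on slides 1, 3 and 4, and the call held with each array left out. Il5ra was at least 1.51-fold higher in VCF. Red blood cell genes differed by a mean of -0.48 (adjusted p = 0.00454). Glucocorticoid and immediate early genes (immediate early below) differed by -0.25 (adjusted p = 0.0275). Both gave adjusted p = 0.818 with an estimated correlation. The mean difference was 0.27 for interferon response genes (adjusted p = 0.000444), 0.27 for T cell genes (adjusted p = 0.00105), 0.39 for neutrophil genes (adjusted p = 0.0138) and 0.30 for monocyte genes (adjusted p = 0.0144). With an estimated correlation each of these gave adjusted p = 0.818. It was 0.31 for natural killer cell genes (adjusted p = 0.0158), 1.25 for thymus genes (adjusted p = 0.0217), 0.80 for liver genes (adjusted p = 0.0217), 0.13 for mesothelial cell genes (adjusted p = 0.0251) and 0.24 for acute phase genes (adjusted p = 0.0346). The last 4 gave adjusted p = 0.818 with an estimated correlation and natural killer cells adjusted p = 0.866. Rag1 was at least 4.9-fold higher in CCF, above background on 2 of 3 CCF arrays, and 1.48-fold without CCF replicate 3. In all, 12 of 43 lists passed, 9 up and 3 down, and with an estimated correlation camera passed 0, where 1 had an unadjusted p under 0.05; fry passed 0. With the slide as a block the means (adjusted p) were 0.28 for acute phase (0.0335), 0.31 for interferon response (0.000143), -0.30 for immediate early (0.0157), 0.19 for mesothelial cell (0.03), 0.33 for T cell (0.000728), 0.34 for natural killer cell (0.0335), 0.36 for neutrophil (0.0597), 0.37 for monocyte (0.0152), -0.39 for red blood cell (0.0152), 1.24 for thymus (0.0415) and 0.76 for liver (0.0683). Within slides the direction turned for acute phase (-0.31 on slide 3), natural killer cell (-0.33 on slide 1), neutrophil (-0.15 on slide 4) and red blood cell (0.50 on slide 3). Calls were lost besides with no filter on dim probes for acute phase, natural killer cell, neutrophil, monocyte and liver; the position on the slide as a block for acute phase, immediate early and liver; normexp background correction for immediate early, T cell, natural killer cell, neutrophil, thymus and liver; array weights for immediate early, natural killer cell and liver; cyclic loess normalization for thymus and liver; the mean over all probes of a gene for thymus; the replicate block for liver. Omitting VCF replicate 1 ended the list calls for mesothelial cell (0.09), natural killer cell (0.23) and monocyte (0.23). Without VCF replicate 2 the calls ended for acute phase (0.20), immediate early (-0.21), mesothelial cell (0.12), T cell (0.15), natural killer cell (0.09), neutrophil (0.35), monocyte (0.20), thymus (1.19) and liver (0.69). Dropping VCF replicate 3 ended the calls for acute phase (0.18) and liver (0.64). Omitting VCF replicate 4 ended the list calls for acute phase (0.26), immediate early (-0.22) and liver (0.86). Without CCF replicate 1 the calls ended for immediate early (-0.26), mesothelial cell (0.03) and natural killer cell (0.20). Dropping CCF replicate 2 ended the calls for acute phase (0.12), immediate early (-0.29), mesothelial cell (0.14), red blood cell (-0.29), thymus (1.26) and liver (-0.04). Omitting CCF replicate 3 ended the list calls for acute phase (0.03), interferon response (0.17), immediate early (-0.20), mesothelial cell (0.21), T cell (0.19), natural killer cell (0.31), neutrophil (0.12), monocyte (-0.03), red blood cell (-0.21) and thymus (0.60). In the fit without 4 arrays the direction turned for red blood cell (0.32), acute phase (-0.34) and thymus genes (-0.03). The number of lists that passed was 4 without VCF replicate 2, 7 without CCF replicate 2 and 3 without CCF replicate 3. Normexp background correction moved the median of all probes from -0.019 to -0.27 here.

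The comparison of RCF with VCF asks what carbonization and firing together change. Clock genes differed between the 4 RCF and 4 VCF lungs in the same opposite directions, with Arntl at 0.69 (SE 0.14), Per2 at -0.73 (SE 0.17) and Tef at -0.35 (SE 0.11). This list call was lost with an estimated correlation (adjusted p = 0.144), and a second Per2 probe differed by 0.08. Fkbp5, a target of glucocorticoid hormone, differed by -0.98 (SE 0.22). Prdm8, a transcriptional regulator, had the smallest adjusted p, 0.109, at 1.04 (SE 0.15), higher in 4 of 4 arrays. No probe passed in limma, where 1548 had an unadjusted p under 0.05. With the slide as a block 1 probe passed, and 1 without Ctrl replicate 1, VCF replicate 1, CCF replicate 1, CCF replicate 3 or RCF replicate 3. Of 18 clock genes 14 were lower, with a mean of -0.08 and a median of -0.21 (adjusted p = 0.00176, or 0.144 with an estimated correlation). The call held with each array left out, with means from -0.11 (without VCF replicate 1) to -0.05 (without VCF replicate 4). In the mixed form of fry adjusted p = 0.00275. The list's mean was -0.08 with the slide as a block and -0.04, -0.21, -0.07 and 0.01 on slides 1, 2, 3 and 4, where Arntl differed by 0.79, 0.84, 0.30 and 0.81. All 9 red blood cell genes were lower, by a mean of -0.39 (adjusted p = 0.00292, or 0.998 with an estimated correlation), with -0.39 with the slide as a block and -0.68, -0.43, -0.30 and -0.15 on slides 1, 2, 3 and 4. B cell genes differed by 0.21 (adjusted p = 0.0339), interferon response genes by 0.16 and adipose genes by -0.56 (adjusted p = 0.0364 for both). Each gave adjusted p = 0.998 with an estimated correlation. Examples are Cd22, a B cell receptor, at 0.37 (SE 0.16) and Ucp1 of brown fat, above background on 2 of 4 VCF arrays and 0 of 4 RCF arrays, a difference for which no bound above 1 holds without VCF replicate 1. In all, 5 of 43 lists passed, 2 up and 3 down, and with an estimated correlation camera passed 0, where 1 had an unadjusted p under 0.05; fry passed 0. Fits with the slide as a block gave means (adjusted p) of 0.16 for interferon response (0.0532), 0.21 for B cell (0.0185) and -0.56 for adipose (0.0439). Within slides the direction turned for interferon response (-0.04 on slide 2), clock (0.01 on slide 4), B cell (-0.21 on slide 1 and -0.11 on slide 2) and adipose (0.47 on slide 1 and 0.06 on slide 2). Further settings that ended calls were quantile normalization for interferon response; cyclic loess normalization for interferon response; the replicate block for interferon response, B cell and adipose; array weights for interferon response, B cell and adipose; the mean over all probes of a gene for interferon response, B cell and adipose; the authors' deposited table for adipose; only probes well above background on all 14 arrays for adipose; only the groups compared in the fit for adipose. Leaving out VCF replicate 1 ended the list calls for interferon response (0.07), B cell (0.15) and adipose (0.01). Calls ended without VCF replicate 2 for interferon response (0.09), B cell (0.02) and adipose (-0.58). With VCF replicate 4 left out the calls ended for red blood cell (-0.29). Leaving out RCF replicate 1 ended the list calls for interferon response (0.13) and B cell (0.17). Calls ended without RCF replicate 2 for interferon response (0.14), B cell (0.17) and adipose (-0.46). With RCF replicate 4 left out the calls ended for adipose (-0.44). The list count was 3 without VCF replicate 2, RCF replicate 1 or RCF replicate 2.

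The comparison of RCF with CCF asks what firing adds to carbonization. Eosinophil transcripts were higher after RCF (4 arrays) than after CCF (3 arrays), with Alox15 at 2.09 (SE 0.42) and Ear6 at 0.57 (SE 0.18), each higher in 4 of 4 arrays. Alox15 was well above background on 1 of 3 CCF arrays. The list call was lost with an estimated correlation (adjusted p = 0.117), and neither gene passed over all probes. Il5ra was well above background on 4 of 4 RCF arrays and 0 of 3 CCF arrays, at least 1.78-fold higher. Glucocorticoid and immediate early genes were higher, with the transcription factors Egr2 at 0.88 (SE 0.20) and Nr4a1 at 1.02 (SE 0.39). That call was also lost (adjusted p = 0.867). Per2 differed by -0.73 (SE 0.18), its second probe by 0.04, and Tef by -0.41 (SE 0.12). S100a9, a calcium-binding protein of neutrophils, differed by -0.87 (SE 0.51), by -0.58 without RCF replicate 3 and -0.02 on slide 4, and the killer cell gene Prf1 by -1.08 (SE 0.32), with 0.04 on slide 4. No probe passed in limma, where 2312 had an unadjusted p under 0.05 and the smallest adjusted p was 0.415. 3 probes passed without CCF replicate 3 and 1 without RCF replicate 2.

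Of 6 eosinophil genes 5 were higher, by a mean of 1.00 (adjusted p = 0.000971, or 0.117 with an estimated correlation). fry passed this list (adjusted p = 0.0213), and adjusted over the list alone 3 genes passed, against 0 over all genes tested. The mean was 0.96 with the slide as a block and 0.64, 1.68 and 0.88 on slides 1, 3 and 4, and the call held with each array left out. Of 18 clock genes 13 were lower. Their mean was 0.00 while their median was -0.29 and the test pointed down (adjusted p = 0.00345, or 0.157 with an estimated correlation), with each array left out as well, when the mean ran from -0.11 (without CCF replicate 2) to 0.11 (without CCF replicate 1). In the mixed form of fry adjusted p = 0.000392. The mean difference was -0.67 for neutrophil genes (adjusted p = 0.000971), -0.20 for cell division genes (adjusted p = 0.00255), -0.38 for acute phase genes (adjusted p = 0.0108), -0.23 for T cell genes (adjusted p = 0.0108), -0.32 for natural killer cell genes (adjusted p = 0.0209), -0.28 for monocyte genes (adjusted p = 0.0256) and -0.06 for heat shock genes (adjusted p = 0.034). With an estimated correlation these gave adjusted p = 0.867, 0.867, 0.835, 0.867, 0.867, 0.867 and 0.867 in that order. It was 0.30 for B cell genes (adjusted p = 0.0136), 0.34 for immediate early genes (adjusted p = 0.0136) and 0.28 for alveolar macrophage genes (adjusted p = 0.0238), each with adjusted p = 0.867 with an estimated correlation. Siglecf, which both the eosinophil and the alveolar macrophage list hold, differed by 1.16 (SE 0.51) (0.40 without CCF replicate 2 and -0.01 on slide 3), and Ms4a1, the B cell antigen CD20, by 0.77 (SE 0.32). In all, 12 of 43 lists passed, 4 up and 8 down, and with an estimated correlation camera passed 0, where 2 had an unadjusted p under 0.05; fry passed 1. The means (adjusted p) with the slide as a block were -0.42 for acute phase (0.00508), -0.04 for heat shock (0.052), -0.27 for cell division (0.000134), 0.01 for clock (0.00508), 0.39 for immediate early (0.013), -0.29 for T cell (0.00508), 0.27 for B cell (0.0206), -0.36 for natural killer cell (0.0346), -0.64 for neutrophil (0.00508), -0.35 for monocyte (0.0195) and 0.25 for alveolar macrophage (0.081). Within slides the direction turned for acute phase (0.40 on slide 3), heat shock (0.39 on slide 1), cell division (0.01 on slide 3), clock (0.01 on slide 1 and 0.23 on slide 4), natural killer cell (0.15 on slide 4), neutrophil (0.10 on slide 4) and monocyte (0.14 on slide 4). Calls did not hold either with no filter on dim probes for heat shock, natural killer cell and monocyte; the replicate block for heat shock and alveolar macrophage; only the groups compared in the fit for heat shock; normexp background correction for immediate early, T cell, natural killer cell and alveolar macrophage; the position on the slide as a block for B cell; the mean over all probes of a gene for monocyte; quantile normalization for alveolar macrophage; cyclic loess normalization for alveolar macrophage. Omitting Ctrl replicate 1 ended the list calls for heat shock (-0.06). Without Ctrl replicate 2 the calls ended for heat shock (-0.06). Dropping CCF replicate 1 ended the calls for heat shock (0.12) and natural killer cell (-0.21). Omitting CCF replicate 2 ended the list calls for acute phase (-0.27), heat shock (-0.02), B cell (0.26) and alveolar macrophage (0.21). Without CCF replicate 3 the calls ended for acute phase (-0.17), cell division (-0.08), immediate early (0.29), T cell (-0.16), natural killer cell (-0.33), neutrophil (-0.40), monocyte (0.04) and alveolar macrophage (0.24). Dropping RCF replicate 1 ended the calls for heat shock (-0.07), cell division (-0.10) and monocyte (-0.23). Omitting RCF replicate 2 ended the list calls for heat shock (-0.01) and B cell (0.25). Without RCF replicate 3 the calls ended for natural killer cell (-0.28) and monocyte (-0.20). Dropping RCF replicate 4 ended the calls for heat shock (-0.03) and alveolar macrophage (0.25). Acute phase genes turned to 0.30 in the fit without 4 arrays. The number of lists that passed was 5 without CCF replicate 3. Normexp background correction moved the median of all probes from 0.008 to 0.221 here, and under it the cell division gene Top2a, -0.76 (SE 0.31), stood at 0.34. A second Top2a probe differed by 0.51 in the main fit.

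The average of the 3 fibre groups against Ctrl asks what the fibres have in common. Across the 11 fibre lungs red blood cell transcripts were higher than in the 3 Ctrl lungs, with Alas2 at 1.84 (SE 0.38) and Hba-a1 at 1.48 (SE 0.26), each higher than the Ctrl mean in 11 of 11 arrays. With an estimated correlation the list call was lost (adjusted p = 0.248). Hbb-bt, an adult beta-globin gene, was read by 4 probes, which differed by 1.98 (SE 0.32), 1.26 (SE 0.27), 1.11 (SE 0.20) and 0.72 (SE 0.19). Its paralogs are nearly identical in sequence, and which copy each probe reads was not tested. Alveolar macrophage transcripts were lower, with Pparg at -0.35 (SE 0.09), Krt79 at -0.56 (SE 0.16) and Ear1 at -0.52 (SE 0.16), and so were Mt2 at -0.92 (SE 0.16) and Hmox1 at -0.47 (SE 0.12), each lower in 11 of 11 arrays. Those 2 list calls were lost as well (adjusted p = 0.128 and 0.237), and Hmox1 was -0.28 without Ctrl replicate 1. 1 probe passed in limma, Olfr1495 at 2.14 (SE 0.24, adjusted p = 0.0297), where 1950 had an unadjusted p under 0.05. It was well above background in 11 of 11 fibre and 1 of 3 Ctrl arrays, so the size of its difference rests on Ctrl signals near background.

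The mean of the 9 red blood cell genes was 0.92 (adjusted p = 1.29e-10, or 0.248 with an estimated correlation), and 1.04 with the slide as a block. Of 15 alveolar macrophage genes 15 were lower, by a mean of -0.33 (adjusted p = 3.28e-07, or 0.128 with an estimated correlation), and -0.28 with the slide as a block. fry passed that list (adjusted p = 0.0206). Of 23 oxidative stress genes 22 were lower, by a mean of -0.27 (adjusted p = 1.04e-06, or 0.237 with an estimated correlation), and all 27 cell division genes by -0.27 (adjusted p = 1.13e-06, or 0.633 with an estimated correlation). Phagocyte genes differed by -0.18 (adjusted p = 0.00866, or 0.633 with an estimated correlation) and smooth muscle genes by 0.16 (adjusted p = 0.0209, or 0.622 with an estimated correlation). Adjusted over the list alone 5 red blood cell, 3 alveolar macrophage and 2 oxidative stress genes passed, and 0 of each over all genes tested. In an exact permutation test of the list scores, added after the data were seen and two-sided, the oxidative stress list had p = 0.00275, the smallest that 364 splits allow, and the red blood cell and alveolar macrophage lists p = 0.011. Adjusted over 43 lists these are 0.118, 0.158 and 0.158. In all, 6 of 43 lists passed, 2 up and 4 down, and with an estimated correlation camera passed 0, where 3 had an unadjusted p under 0.05; fry passed 1. With the slide as a block the means (adjusted p) were -0.15 for phagocyte (0.0161), -0.29 for oxidative stress (2.92e-07), -0.20 for cell division (0.000544) and 0.15 for smooth muscle (0.0286). Also ending calls were normexp background correction for phagocyte; array weights for phagocyte and smooth muscle. Leaving out Ctrl replicate 1 ended the list calls for phagocyte (-0.10), oxidative stress (-0.14), cell division (-0.15) and smooth muscle (0.09). Calls ended without Ctrl replicate 2 for phagocyte (-0.13). The list count was 3 without Ctrl replicate 1 and 21 without Ctrl replicate 3. Olfr1495 differed by 2.01 with the slide as a block (adjusted p = 0.238), and by 0.27 with normexp background correction. Its call ended without Ctrl replicate 1 (2.30), Ctrl replicate 2 (2.06), Ctrl replicate 3 (2.06), VCF replicate 3 (2.10), VCF replicate 4 (2.14), CCF replicate 2 (2.11), RCF replicate 1 (2.13) or RCF replicate 3 (2.17), when no probe passed. The count of probes was 2 without VCF replicate 1 or RCF replicate 4, 10 without CCF replicate 1 and 12 without CCF replicate 3.

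**Figure D2:**
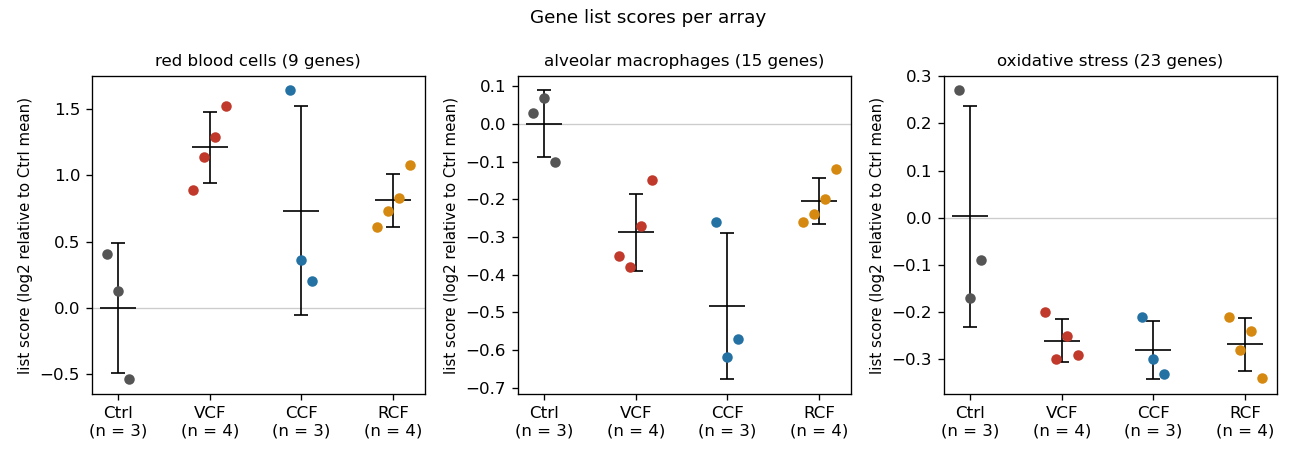
Mean log2 score of the red blood cell, alveolar macrophage and oxidative stress lists on each array by group, relative to the Ctrl mean, with bars for the mean and SD of each group. All 11 fibre arrays lie below every Ctrl array in the alveolar macrophage score, and 9 of 11 above every Ctrl array in the red blood cell score.

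Probes whose arrays of the 2 groups did not overlap made up 8.68%, 9.76% and 8.05% in VCF, CCF and RCF against Ctrl, where chance gives 5.71%, 10% and 5.71%. They were 5.28% in CCF against VCF (chance 5.71%), 3.89% in RCF against VCF (chance 2.86%), 8.63% in RCF against CCF (chance 5.71%) and 0.73% in the average of the fibre groups (chance 0.55%).

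The 3 comparisons with Ctrl share the same 3 Ctrl arrays. Across probes the VCF and CCF differences correlated at r = 0.62, VCF and RCF at 0.64 and CCF and RCF at 0.52. Arrays stripped of their group means and dealt at random to the labels 100 times gave mean r of 0.53, 0.58 and 0.53 (95% of them from 0.11 to 0.82, 0.07 to 0.85 and 0.16 to 0.83), so r of this size can arise without a fibre effect. The dealing took no account of the slides. The 3 Ctrl arrays are too few to be divided between the comparisons. Genes are not independent replicates.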

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

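Of the tests weighed here, those of the slide, of the Olfr1495 probe and of dilution by other tissue were chosen only after the result was seen. The tests of carried red cell RNA, of time of day and of other splits of the arrays were written before.

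Red blood cell transcripts were higher in the 3 fibre groups, by a mean of 0.92 (log2) over 9 genes (adjusted p = 0.248 with an estimated correlation, so the camera call is lost there, and 0.158 in the exact permutation of list scores), 8 of which stood above background in every Ctrl lung and 0 of which another list holds. A difference between slides as the whole cause is argued against by the value with the slide as a block, 1.04. Red cell RNA carried in blood left in the lung stays open as a candidate source: within groups the 9 genes moved together from array to array, with a median pairwise correlation of 0.73, as a varying blood content would give, and a biological rise with the fibre would not be told from it by this test. The brightest genes were Hbb-bt, at 8.13 in Ctrl and 8.85 in the fibre groups, and Hba-a1, at 6.75 and 8.23 (normalised log2 signal). The labels name no perfusion step that would remove blood. Whether the Olfr1495 probe follows red cell RNA was not decided, since the correlation fell between the 2 predictions (r = 0.34, permutation p = 0.4, adjusted 0.4; rho = 0.23, permutation p = 0.522; r = 0.16 without CCF replicate 1 and Ctrl replicate 3).

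Alveolar macrophage transcripts were lower in the 3 fibre groups, by a mean of -0.33 over 15 genes (adjusted p = 0.128 with an estimated correlation, so the camera call is lost there), 6 of which another list also holds and 15 of which stood above background in every Ctrl lung. Dilution by other tissue as the whole cause is argued against by a median shift of 0.04 in 5 other lung cell lists. Partial dilution stays open (alveolar type 1 0.04, type 2 -0.09). A slide difference as the whole cause is argued against by the slide-block value, -0.28. Fewer such cells, or lower expression per cell, after fibre of any form may account for it and was not tested, and the exact permutation of list scores gave adjusted p = 0.158.

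Clock transcripts differed between RCF and the other groups, with Arntl against Tef, Per2 and Ciart; the list passed in camera for RCF against Ctrl, VCF and CCF but not with an estimated correlation (adjusted p = 0.171, 0.144 and 0.157), and none of these genes passed over all probes. A second Per2 probe differed by 0.27, 0.08 and 0.04, opposite to the first. A difference in the time of day at which lungs were taken may give this, and it could not be separated from the group: within groups Arntl correlated with the mean of the other clock genes at r = -0.45 (permutation p = 0.148, adjusted 0.296) and rho = -0.49 (permutation p = 0.12), and at -0.39 without CCF replicate 1 and Ctrl replicate 2, over 14 arrays. The labels give no time of day, and an effect of the fibre on the clock was not tested. These 2 correlations are the only ones computed in their family.

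Some gene lists passed in camera between 2 fibre groups and also passed for at least 1 of those 2 against Ctrl, the shared reference. They are given by their mean difference (log2), with the adjusted p from an estimated correlation in parentheses, and other lists that passed between the fibres are in the comparisons above. For CCF against VCF these were acute phase genes at 0.24 (0.818), interferon response genes at 0.27 (0.818), monocyte genes at 0.30 (0.818), eosinophil genes at -0.79 (0.128), red blood cell genes at -0.48 (0.818), thymus genes at 1.25 (0.818) and liver genes at 0.80 (0.818). For RCF against VCF these were interferon response genes at 0.16 (0.998), clock genes at -0.08 (0.144), red blood cell genes at -0.39 (0.998) and adipose genes at -0.56 (0.998). For RCF against CCF these were acute phase genes at -0.38 (0.835), cell division genes at -0.20 (0.867), clock genes at 0.00 (0.157), neutrophil genes at -0.67 (0.867), monocyte genes at -0.28 (0.867), alveolar macrophage genes at 0.28 (0.867) and eosinophil genes at 1.00 (0.117). The arrays whose omission ends each call stand in the comparisons above, with the value without them.

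Among 315 groups of 4 arrays, 12 (3.8%) held an array apart from the rest by more than Dixon's 95% critical value for 4 values, where chance gives about 5%. Values are normalised log2 signals, and for the list its score, with the range of the other arrays. Trem2 in VCF replicate 4 was at 1.42 (others 0.81 to 0.91) and Bub1 in VCF replicate 2 was at -1.89 (others -1.35 to -1.28). Retn in VCF replicate 1 was at 0.26 (others -2.62 to -2.16) and Slc16a10 in VCF replicate 1 was at -5.00 (others -5.33 to -5.28). Map2k6 in VCF replicate 4 was at -1.23 (others -1.80 to -1.74) and Medag in VCF replicate 4 was at -0.58 (others -0.33 to -0.28). Thrsp in VCF replicate 1 was at 1.67 (others -0.39 to -0.16) and Ccnjl in VCF replicate 1 was at -2.55 (others -1.85 to -1.71). Hspb8 in RCF replicate 2 was at 1.27 (others 1.58 to 1.62) and Cyp1b1 in RCF replicate 3 was at -1.18 (others -0.90 to -0.85). Pdgfrb in RCF replicate 4 was at 2.66 (others 3.13 to 3.17) and glucocorticoid and immediate early genes in RCF replicate 2 was at 0.13 (others 0.23 to 0.24).

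Other splits of the same arrays tell whether chance can be excluded. Chance cannot be excluded for the 3 probes of VCF against Ctrl, since 2 of 35 splits gave as many (highest other split 3), nor for the 10 lists, with 19 of 35 (highest other 21). For CCF against Ctrl the splits are too few for a share under 0.05: the real counts were 0 probes and 8 lists, the highest others 1 and 18, and 10 and 7 of 10 splits gave as many. Where the real count is 0 probes, in RCF against Ctrl and the 3 pairs of fibres, all 35 of 35 splits give as many by construction, which decides nothing (highest others 1, 2, 2 and 2). Chance cannot be excluded for the 8 lists of RCF against Ctrl, with 21 of 35 (highest other 20), the 12 of CCF against VCF, with 11 of 35 (highest other 19), the 5 of RCF against VCF, with 23 of 35 (highest other 23), or the 12 of RCF against CCF, with 8 of 35 (highest other 17). For the average of the 3 fibre groups, of 364 possible splits 100 were drawn: 9 gave as many as 1 probe (highest other 4) and 72 as many as 6 lists (highest other 22). Chance can be excluded for none of the counts that could be tested. Splits that follow the slides gave as many lists as the real one in some cases and fewer in others. They ran from 2 to 11 for VCF and Ctrl, 6 to 18 for CCF and Ctrl and 6 to 13 for RCF and Ctrl. They ran from 1 to 18 for CCF and VCF, 3 to 13 for RCF and VCF and 1 to 12 for RCF and CCF. Slide-block values stand by each list. Splits with more lists may reflect sample structure beyond the groups, or correlation within lists beyond the preset 0.01. Neither was tested on the splits. Red blood cell genes had a median r of 0.73 within groups.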

How the results depend on the processing

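The fit without 4 arrays and the permutation of list scores were chosen only after the result was seen. The other tests were planned. Of 8921 values of named genes under the alternatives, 8775 kept direction and side of the threshold. Of these genes only Olfr1495 had passed and most were picked by p on these arrays, so that is largely built in. 35 newly passed, 28 no longer passed and 83 changed sign, 0 of these with a pass in either fit. Causes not given were not tested. The red blood cell and alveolar macrophage calls against Ctrl held under each array left out, though the red blood cell mean of CCF ran from 0.28 to 1.00. The number of arrays, and signal near background for Olfr1495, Il5ra, Rag1, Alox15 and Fgb, limit these values. Asking for a 2-fold difference too left the adjusted p counts the same.

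Counts that moved by over 1.5 times are these. With normexp background correction the number of probes was 0 (VCF against Ctrl and 3 fibre groups against Ctrl) and the number of lists was 17 (VCF against Ctrl and RCF against Ctrl) and 13 (3 fibre groups against Ctrl). With quantile normalization the number of probes was 0 (VCF against Ctrl and 3 fibre groups against Ctrl). With cyclic loess normalization the number of probes was 0 (VCF against Ctrl and 3 fibre groups against Ctrl). From the authors' deposited value table the number of probes was 6 (VCF against Ctrl). With no filter on dim probes the number of probes was 5 (VCF against Ctrl), 1 (RCF against Ctrl) and 2 (3 fibre groups against Ctrl). For probes well above background on all 14 arrays the number of probes was 0 (3 fibre groups against Ctrl) and the number of lists was 5 (CCF against Ctrl). With the slide as a block the number of probes was 1 (VCF against Ctrl and RCF against VCF) and 0 (3 fibre groups against Ctrl). With the position on the slide as a block the number of probes was 1 (CCF against Ctrl and RCF against Ctrl) and 2 (3 fibre groups against Ctrl). With the replicate block the number of probes was 6 (VCF against Ctrl) and 0 (3 fibre groups against Ctrl) and the number of lists was 14 (RCF against Ctrl) and 2 (RCF against VCF). With only the groups compared in the fit the number of probes was 1 (VCF against Ctrl). With an intensity trend and a robust prior the number of probes was 5 (3 fibre groups against Ctrl). With array weights the number of probes was 7 (VCF against Ctrl), 1 (RCF against Ctrl) and 3 (RCF against VCF and 3 fibre groups against Ctrl) and the number of lists was 4 (CCF against Ctrl) and 3 (RCF against VCF). With camera with an estimated correlation the number of lists was 0 in each comparison. In fry the number of lists was 0 (VCF against Ctrl, RCF against Ctrl, CCF against VCF and RCF against VCF) and 1 (CCF against Ctrl, RCF against CCF and 3 fibre groups against Ctrl). With the mean over all probes of a gene the number of lists was 2 (RCF against VCF). With the 4 arrays with other-tissue transcripts left out the number of probes was 0 (VCF against Ctrl and 3 fibre groups against Ctrl) and the number of lists was 16 (CCF against Ctrl), 7 (CCF against VCF) and 11 (3 fibre groups against Ctrl). At an unadjusted p under 0.05 the number of probes was 2417 (VCF against Ctrl), 1930 (CCF against Ctrl), 1564 (RCF against Ctrl), 1699 (CCF against VCF), 1548 (RCF against VCF), 2312 (RCF against CCF) and 1950 (3 fibre groups against Ctrl). In the plain 2-sample test with adjustment the number of probes was 0 (VCF against Ctrl and 3 fibre groups against Ctrl). In the fit without 4 arrays CCF keeps 1 array, assumed to vary like the other groups, so counts there with CCF decide nothing.

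With each array left out in turn, the number of probes ran from 0 to 16 (VCF against Ctrl), 0 to 1 (RCF against VCF), 0 to 12 (3 fibre groups against Ctrl), 0 to 10 (RCF against Ctrl), 0 to 1 (CCF against VCF), 0 to 3 (RCF against CCF) and 0 to 1 (CCF against Ctrl). The number of lists ran from 3 (VCF against Ctrl, without Ctrl replicate 1) to 18 (without Ctrl replicate 3), 4 (CCF against Ctrl, without Ctrl replicate 1) to 14 (without Ctrl replicate 3), 3 (3 fibre groups against Ctrl, without Ctrl replicate 1) to 21 (without Ctrl replicate 3), 7 (RCF against Ctrl, without Ctrl replicate 1) to 19 (without Ctrl replicate 3), 3 (CCF against VCF, without CCF replicate 3) to 13 (without Ctrl replicate 3), 3 (RCF against VCF, without VCF replicate 2) to 7 (without RCF replicate 3) and 5 (RCF against CCF, without CCF replicate 3) to 14 (without CCF replicate 1). Fewer arrays change the spread and the prior as well as the means.

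Named genes that turned sign with 1 array left out, none of which passed, ran as follows, with the array whose omission took them furthest past 0. VCF against Ctrl: Spp1 -0.19 to 0.24 (without Ctrl replicate 3), Col1a1 -0.38 to 0.10 (without Ctrl replicate 1) and Cyp1a1 -1.94 to 0.18 (without Ctrl replicate 1). CCF against Ctrl: Alox15 -0.61 to 0.09 (without CCF replicate 1), Prss16 -0.17 to 0.35 (without CCF replicate 3), Gpnmb -0.64 to 0.07 (without CCF replicate 2), Cxcl1 -0.84 to 0.50 (without CCF replicate 1), Saa3 -1.52 to 0.27 (without CCF replicate 1), Col1a1 -0.26 to 0.21 (without Ctrl replicate 3) and Cyp1a1 -1.95 to 0.17 (without Ctrl replicate 1). RCF against Ctrl: Mmp12 -0.75 to 0.01 (without Ctrl replicate 1), Cxcl1 -0.40 to 0.30 (without Ctrl replicate 1), Col1a1 -0.15 to 0.33 (without Ctrl replicate 3) and Cdkn1a -0.11 to 0.09 (without Ctrl replicate 1). CCF against VCF: Alb -0.39 to 1.83 (without CCF replicate 2). RCF against VCF: Thrsp -0.65 to 0.04 (without VCF replicate 1). 3 fibre groups against Ctrl: Cnn1 -0.03 to 0.64 (without Ctrl replicate 1).

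Values of the opposite sign include these, in log2, or of the opposite direction in the test for thymus genes in CCF against Ctrl. With normexp background correction the opposite sign was found for Spp1 -0.10 (VCF against Ctrl), Olfr1495 -0.11, Taar4 -0.22, Ctsd 0.06, Themis -0.32, Prss16 -0.56, Apoa2 -0.05 and Cyp2c29 -0.50 (CCF against Ctrl), Plekho2 -0.45, Slc16a10 -0.58, Atrnl1 -0.41, Zfp385b -0.45, Nxph1 -0.47, Cd3e -0.20, Eomes -0.35, Prss16 -0.71, Themis -0.56 and Cyp2c29 -0.61 (CCF against VCF) and Pogk 0.20, Wee1 0.40, Top2a 0.34, Bub1 0.01, Trat1 0.16, Cd3e 0.12, Eomes 0.40 and Ncr1 0.13 (RCF against CCF). With the 4 arrays with other-tissue transcripts left out the opposite sign was found for thymus 0.01, Dntt -0.48 and Prss16 -0.11 (CCF against Ctrl), acute phase and innate defence -0.34, red blood cells 0.32, thymus -0.03, Saa2 -0.57, Lcn2 -0.13, Ccr2 -0.20, Hba-a1 0.30, Alas2 0.34 and Dntt -0.73 (CCF against VCF), acute phase and innate defence 0.30, Saa2 0.34, Saa1 0.45, Cd22 -0.05, Ccr2 0.15 and Cd9 -0.01 (RCF against CCF), Spp1 -0.07 and Col1a1 0.00 (VCF against Ctrl) and Cxcl1 0.18 and Cdkn1a 0.03 (RCF against Ctrl). With the slide as a block the opposite sign was found for Spp1 -0.01 and Col1a1 0.00 (VCF against Ctrl), Cxcl1 0.12 and Saa3 0.21 (CCF against Ctrl) and Cxcl1 0.13 and Cdkn1a 0.06 (RCF against Ctrl). With array weights the opposite sign was found for Cxcl1 0.10 (CCF against Ctrl) and Cdkn1a 0.02 (RCF against Ctrl). Normexp moved the median of all probes from -0.015 to -0.226 in CCF against Ctrl, from -0.019 to -0.27 against VCF and from 0.008 to 0.221 in RCF against CCF, so the CCF values with normexp are to be read against that shift, and the cause was not tested. Of the genes named in the text besides Per2 and Col1a1, second probes stood opposite to the first in the main fit for Ctsd 0.00 (CCF against Ctrl), Slc16a10 -0.10 (CCF against VCF) and Top2a 0.51 and Bub1 0.08 (RCF against CCF).

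Replicate numbers do not pair the arrays: 19 pairs of the same number had residuals correlated at a mean of 0.01 (-0.37 to 0.35), and the replicate block moved the numbers of probes to 6 in VCF against Ctrl and 0 in the average of the fibre groups. The 18 pairs that share a slide had a mean of 0.17, against -0.05 for 55 that do not, so the slide as a block is given beside each list and Olfr1495. The correlation of the VCF and CCF differences ran from 0.57 to 0.72 over its alternatives.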

Other observations

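The lists below were fixed before the data were examined, and were picked for this part only after the result was seen. In the average of the 3 fibre groups against Ctrl, alveolar type 1 cell genes differed by a mean of 0.04, alveolar type 2 cell genes, which make surfactant, by -0.09, endothelial cell genes by 0.03 and ciliated cell genes by 0.07. Fibroblast genes differed by 0.17 and B cell genes by -0.04. None of these lists passed in that comparison.

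Pairs of arrays of the same group correlated at 0.972 to 0.988 across probes, and pairs of different groups at 0.968 to 0.99, so no 2 arrays were duplicates by this measure.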
